A study of Mus musculus with 7 samples.

How the data were processed

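Astrocytes were purified from whole mouse brains with a magnetic ACSA-2 kit, and their purity by flow cytometry for GFAP exceeded 70%, per the labels' protocols. Biotin-labelled cRNA was made from 10 ng of total RNA with the Affymetrix Pico procedure, per the labels. The labels give each array its own animal number.

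The deposited value table holds log2 values made by the authors, 1 per probe set and array, between 2.74 and 19.6. The summarization, background correction and normalization are not given in the sources used here. Base 2 was taken from the values, because differences between group averages equalled log2 of the folds in the authors' deposited fold table. That table holds signed linear folds between 2 unnamed groups and comes from a QIAGEN product, per the file headers. The fold was compared with mean and Tukey biweight averages (constant 5) of each pair of groups. Scanner files were not used here.

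Of 28846 entries in the value table, 22206 transcript cluster probe sets were kept, and 5222 negative control, 1324 positive control and 23 background entries were left out with the other controls. A full table of probe sets and genes was not used here. The test design had assumed gene names for all probe sets, and names were taken instead from the fold table, which pairs 1778 probe sets with symbols. These were matched to the RefSeq table of assembly GRCm38.p6, used for names only. Of the 1778 entries, 1522 matched a gene on the chromosome that the probe set's ID names. For 78 the symbol was not found and the file's name was kept, and 3 had no chromosome in the ID. Another 11 were dropped because the gene lies on another chromosome, and 164 because they name several genes. That left 1603 probe sets and 1592 genes. For a gene with several probe sets the one with the highest mean was used, giving 22195 features.

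Groups were taken from the labels. A single limma model with 3 group means was fitted to all 7 arrays with lmFit and eBayes (limma 3.58.1, R 4.3.3), with no covariate, and 4 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The residual degrees of freedom were 4 and the prior ones 5.39. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, if at least 3 members were named. With an estimated correlation camera called 0 lists in any of the 4 contrasts. All p-values are two-sided. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

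The 35 lists, with 452 symbols of which 78 were named, covered cholesterol and lipid pathways, astrocyte functions and reactive states, stress and quality signs, and markers of brain cell types. In 7 lists no member was named, and in 13 others 1 or 2 were. Named genes followed a rule set before the data were examined. It takes, per direction, 10 genes in the first contrast and 5 in the others, by size among those past the threshold whose arrays do not overlap, filled up by smallest unadjusted p. It adds up to 4 members per list past the threshold when adjusted over the list alone, or else the 2 of smallest p, and 12 fixed genes in the first contrast, of which 5 were named here. The text gives some of these and leaves out or summarises the rest. Another 4 genes chosen by these rules are not reported here, though they were kept as members of their lists.

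The tests were checked on simulated data with 200 changed genes among 22195 features. With no change simulated in the second contrast, lists of these named genes gave an unadjusted p under 0.05 in 11.5% of tests and at least 1 called list in 28 of 100 draws, while random lists of the same sizes gave 3.8%. Camera thus called lists of these selected genes too often even there. The simulation drew independent noise around each gene's mean, with neither co-expression nor the authors' selection, so it does not give the rate of false calls in these data. Alternatives were leaving out each array, fitting only the groups compared, pooling the 5 CETP arrays, quantile normalization, median subtraction, a filter on dim features, averaging probe sets, array weights, a trended robust prior, blocks by replicate number and by the first digit of the animal number, other thresholds, an estimated correlation and fry. A covariate for the hybridization spike-in level was added after seeing the data.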

Results

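Gene expression was measured in astrocytes taken from the brains of 7 mice, with 1 single-colour Affymetrix array for each animal. Astrocytes are the glial cells that make most of the brain's cholesterol and pass it to neurons on apolipoprotein E particles. The CETP strain carries the human gene for cholesteryl ester transfer protein, a plasma protein that moves cholesteryl esters between lipoproteins and that mice lack. The arrays form 3 groups: wild type on a standard diet (n = 2, replicates 2 and 3), CETP transgenic on a diet with 1% cholesterol (n = 3, replicates 1, 2 and 3) and CETP transgenic labelled as standard diet (n = 2, replicates 4 and 5). The labels' growth protocol gives the cholesterol diet, fed for 2 months from the age of 2 to 4 months, for transgenic animals as such, so the diet of the last group rests on its own label. The number of arrays limits the precision of every value.

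Each array gave log2 values for 22206 probe sets of transcript clusters, with medians between 7.51 and 7.59. Negative controls had medians of 7.48 to 7.69 on the arrays. A value under that level may be background, and the size of a difference from it is uncertain. No test of detection was run. Pairwise correlations across probe sets ran from 0.977 to 0.992. Gene names were at hand for 1592 genes. All of these came from the authors' deposited fold table, which lists probe sets that differed at least 1.4-fold between the CETP diet groups. A list of named genes is therefore not independent evidence of a difference between those groups. Comparisons of a CETP group with wild type share its arrays and are affected as well. Across the table's probe sets, its log2 folds correlated with the difference from wild type at r = -0.565 for the cholesterol diet and 0.554 for the standard-diet label. Lists fixed before the data were examined had too few named genes for a test in 20 of 35 cases, leaving 15.

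The first comparison set CETP mice on the cholesterol diet against wild type on the standard diet, the comparison that the series' design text states. It asks what astrocytes express when transgene and dietary cholesterol are combined, and genotype and diet cannot be separated in it. No gene passed the test. The following are some of the 10 genes per direction ranked first by unadjusted p, among those whose arrays did not overlap between groups. The topoisomerase gene Top1, whose enzyme relaxes DNA during transcription, measured 8.53 ± 0.10 (SD, n = 3) against 9.55 ± 0.13 (SD, n = 2), a log2 difference of -1.02 ± 0.19 (SE). Also on the lower side were Zc3h15 at -1.36 ± 0.24 and the glycerol kinase gene Gk at -1.30 ± 0.26. On the higher side Hif3a of the hypoxia-inducible factor family differed by 1.43 ± 0.29 and Mylk, myosin light chain kinase, by 1.43 ± 0.34. The transcription factor genes Foxo3 and Foxo4, targets of insulin signalling, also ranked high on that side. Foxo3 lay at or below the negative control median on both wild-type arrays and 1 cholesterol-diet array, and Foxo4 on all 7 arrays.

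Cholesterol genes lay on both sides of the wild-type level in these animals, and none passed the test. Srebf2, the transcription factor that drives cholesterol synthesis, had a log2 difference of 0.48 ± 0.27. Mvk, mevalonate kinase, stood at 0.52 ± 0.21 and the sterol isomerase gene Ebp at -0.70 ± 0.34. Srebf1, the regulator of fatty acid synthesis, differed by 0.40 ± 0.32, the lipoprotein receptor gene Lrp1 by 0.21 ± 0.27 and Apoe by -0.25 ± 0.24. With the hybridization spike-in level as a covariate, chosen after seeing the data, the directions of Ebp (0.23), Srebf1 (-0.069), Lrp1 (-0.19) and Apoe (0.017) turned. The spike-in level was itself higher on all 3 cholesterol-diet arrays (11.21 or more) than on both wild-type arrays, so the covariate was partly confounded with the groups. The cholesterol synthesis list had 4 named members of 20, of which 0 passed when adjusted over the list alone, and its median log2 difference was 0.40 (camera adjusted p = 0.161). Sqle, Abca1, Abcg1, Cyp46a1, App, Gfap and Aqp4 were also to be reported, but no probe set carried those names here and they were not analysed.

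**Figure D1:**
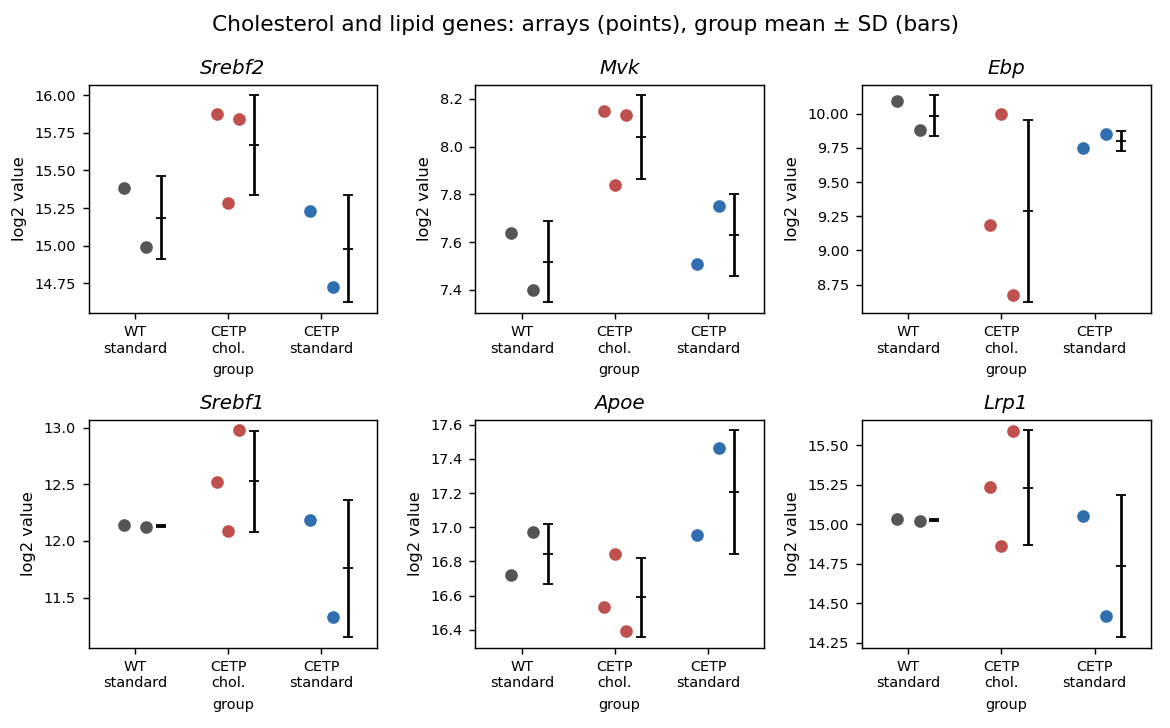
Log2 value of 6 cholesterol and lipid genes (vertical axis of each panel) in the 3 groups (horizontal axis). Points are arrays and bars the group mean ± SD. For Srebf2 the 3 cholesterol-diet arrays lie at 15.28 or more and the 2 CETP standard-diet arrays at 15.23 or less.

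Among the 15 lists tested, chaperone genes of the endoplasmic reticulum had the lowest median. Hspa5, the main chaperone there, differed by -0.85 ± 0.26 and Creld2 by -0.95 ± 0.27, and these 2 of 4 named unfolded protein response genes fell when adjusted over the list alone. The median of that list was -0.69 (camera adjusted p = 0.0514). Of the 5 named heat shock genes 1 fell in the same sense, the mitochondrial co-chaperone Hspe1 (-0.85 ± 0.25), with a list median of -0.52 (camera adjusted p = 0.115). In lists with only 2 named members, and adjusted over these alone, Slc1a3, the GLAST glutamate transporter on which astrocytes are recognised, rose (1.23 ± 0.38). So did the neuronal kinase gene Camk2a (0.86 ± 0.29). In lists of 3 named members, Aplp1, a relative of the amyloid precursor protein gene, rose (0.85 ± 0.25), as did Lcn2, a secreted lipid carrier of reactive astrocytes (2.78 ± 0.94). Lcn2 was at or below the negative control median on both wild-type arrays and 1 cholesterol-diet array. Over all genes tested 0 of the genes in this paragraph passed. The authors had selected each of them for a difference in the same direction between the CETP diet groups. The same cholesterol-diet arrays enter here, so these directions are not independent evidence.

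The microglia list, which marks the brain's resident immune cells, had a median of 0.81 over 8 named genes (camera adjusted p = 0.0514), with C1qb at 1.63 ± 0.83 and C1qa at 1.53 ± 0.97. C1qb was at or below the negative control median on both wild-type arrays and 1 cholesterol-diet array, and C1qa on 1 wild-type array. The interferon response list had a median of 0.27, with Usp18 at 0.30 ± 0.25. Medians were 0.36 for amyloid precursor processing, 0.49 each for glycolysis and lactate transport and for pan-reactive astrocyte genes, 0.28 for endothelial genes, 0.20 each for regulation by SREBP2 and for targets of the liver X receptor, 0.12 for lipoprotein receptors, 0.09 for immediate early genes, -0.34 for disease-associated microglia and -0.54 for choroid plexus. The spike-in covariate turned the medians of lipoprotein receptors (-0.35), glycolysis (-0.33) and disease-associated microglia (0.35). Leaving out wild-type replicate 3 turned the medians of interferon response (-0.044), SREBP2 regulation (-0.041) and liver X receptor targets (-0.041). Leaving out cholesterol-diet replicate 3 turned those of lipoprotein receptors (-0.013) and immediate early genes (-0.010). The SREBP2 and liver X receptor lists share Mylip, and both of their medians given here are the value of that gene. None of the 15 lists was called by camera (limma), and the smallest adjusted p with an estimated correlation was 0.509.

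By limma, 0 of 22195 features passed an adjusted p of 0.05 in the first comparison, and the smallest adjusted p was 0.448. At an unadjusted p under 0.05 there were 1926, of which 747 were higher and 1179 lower, where chance alone gives 1110. The groups did not overlap for 25.1% of features, where chance gives 20.0%. In simulated data the same test found 20.5% of genes changed 2-fold and 98.5% of those changed 4-fold. Among probe sets without a name, TC1800000646.mm.2 had the smallest unadjusted p on the higher side (2.14 ± 0.33) and TC0Y00000558.mm.2 on the lower side (-1.15 ± 0.20).

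The second comparison set CETP mice labelled as standard diet against wild type, which asks about genotype with the diet label held equal. No gene passed the test, and the following are again the genes ranked first by unadjusted p. Ly6e, an interferon-induced membrane protein gene, measured 14.42 ± 0.22 (SD, n = 2) against 12.83 ± 0.22 (SD, n = 2), a 3.02-fold difference with an SE of 0.23 on the log2 scale. Samd9l differed by 1.44 ± 0.24. Irf7, the transcription factor that amplifies the interferon response, and the GTPase gene Igtp also ranked high, but Irf7 lay below the negative control median on all 7 arrays and Igtp on the 5 arrays outside this CETP group. Ptprb, a receptor phosphatase of vessel walls, differed by 1.56 ± 0.28. Sec14l2 (-0.93 ± 0.22) and Dagla, whose enzyme makes an endocannabinoid (-0.93 ± 0.23), had the smallest p on the lower side.

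As a list the interferon response shifted upward, with a median of 1.05 over 6 named genes (camera adjusted p = 1.1e-09). Its call was lost with an estimated correlation (adjusted p = 0.238 with an estimated correlation). When adjusted over the list alone 5 of the 6 rose, among them Usp18 (0.94 ± 0.27), Ifi44 and Irf7, of which Ifi44 was below the negative control median on 6 arrays and Irf7 on all 7. Psmb8, an interferon-induced proteasome subunit, rose when adjusted over the A1 reactive astrocyte list alone (1.09 ± 0.28), which had only 2 named members. Over all genes its adjusted p by limma was 0.925. It was at or below the negative control median on both wild-type arrays and 1 cholesterol-diet array. Microglial genes shifted upward too, with a median of 2.03 over 8 named genes (camera adjusted p = 5.5e-09; adjusted p = 0.238 with an estimated correlation). Adjusted over the list alone 5 of the 8 rose, among them the complement genes C1qa (3.32 ± 1.07) and C1qb (2.38 ± 0.91) and the signalling adaptor Tyrobp (2.66 ± 0.96). Of the 8 microglial genes 5 were below the negative control median on most arrays.

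The microglial genes were far higher in 1 of the 2 animals. C1qa measured 13.62 in CETP standard-diet replicate 4 and 9.46 in replicate 5, where the other 5 arrays lay between 7.59 and 10.44. Tyrobp measured 10.88 and 6.87 in the same 2 arrays. Without replicate 4 the microglia median fell to 0.54 and its call was lost (camera adjusted p = 0.0538), while the interferon list was still called.

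**Figure D2:**
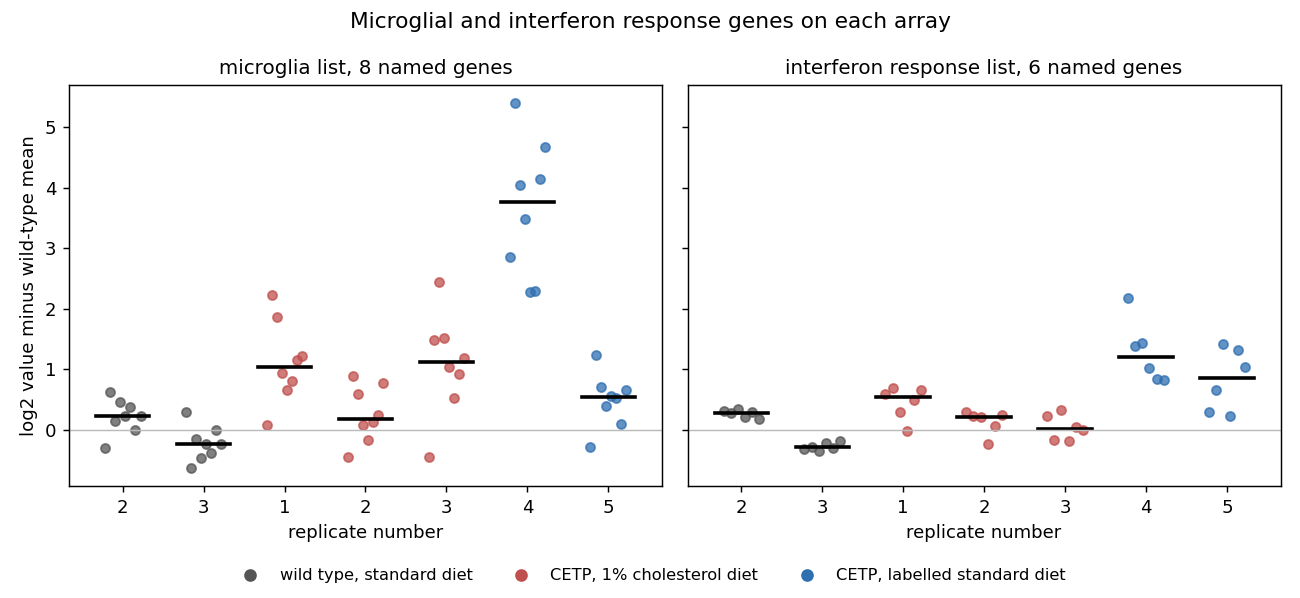
Log2 value minus the wild-type mean (vertical axis) of the 8 named microglia genes and the 6 named interferon response genes on each of the 7 arrays (horizontal axis, replicate number). Points are genes and black lines the median. The microglia median is 3.77 in CETP standard-diet replicate 4 and 0.54 in replicate 5, and the interferon median 1.21 and 0.85.

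Further lists called in the second comparison were endothelial genes (median 0.97, camera adjusted p = 0.000176), immediate early genes (median 1.27, camera adjusted p = 0.00251), disease-associated microglia (median 0.73, camera adjusted p = 0.00785) and pan-reactive astrocyte genes (median 0.84, camera adjusted p = 0.0369). With an estimated correlation the adjusted p was 0.399 for disease-associated microglia and 0.238 for the other 3. The vascular receptor gene Flt1 (1.23 ± 0.30) and the immediate early gene Junb (1.68 ± 0.47) rose when adjusted over their list alone, each of only 3 named members. All 4 calls were lost without replicate 4, where the medians were 0.35, 0.06, -0.08 and 0.11. By limma 0 features passed (smallest adjusted p = 0.614), and 1175 had an unadjusted p under 0.05 where chance gives 1110. In simulated data the test found 0% of genes changed 2-fold and 98.0% of those changed 4-fold.

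The third comparison set the cholesterol diet against the standard-diet label within CETP mice, and also tests whether the first and second comparison differ. Of the 4 named genes of cholesterol synthesis 3 had higher means on the cholesterol diet, and all 6 named interferon genes had lower means. Srebf2 measured 15.67 ± 0.33 (SD, n = 3) against 14.98 ± 0.36 (SD, n = 2), a log2 difference of 0.69 ± 0.27 (SE), and Mvk differed by 0.41 ± 0.21. Rtp4, an interferon-induced chaperone gene, fell when adjusted over its list alone (-0.77 ± 0.27). So did Irf7, which lay below the negative control median on all 7 arrays. The growth factor binding protein gene Igfbp7, abundant in vessels, differed by -0.96 ± 0.21. Every name in this comparison was selected by the authors for a difference between these 2 groups.

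Of the 15 lists 12 were called by camera in the third comparison. Cholesterol synthesis had a median of 0.52 (camera adjusted p = 0.00878), interferon response one of -0.82 (camera adjusted p = 1.33e-08) and the unfolded protein response one of -0.63 (camera adjusted p = 1.74e-05). With an estimated correlation no list was called, and the adjusted p was 0.226 for cholesterol synthesis and 0.219 for the other 2. The cholesterol synthesis call was also lost with the spike-in covariate, chosen after seeing the data. In the unfolded protein response list 2 of 4 fell when adjusted over the list alone, Hspa5 (-0.86 ± 0.26) and Edem1 (-0.58 ± 0.21). The microglia median was -1.22 and turned to 0.35 without CETP standard-diet replicate 4, and 4 lists were then called, among them interferon response and the unfolded protein response but not cholesterol synthesis (median 0.25). By limma 0 features passed (smallest adjusted p = 1.000), and 676 had an unadjusted p under 0.05, fewer than the 1110 chance gives. In simulated data the test found 3.5% of genes changed 2-fold and all 200 changed 4-fold.

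The fourth comparison set the mean of both CETP groups against wild type, the contrast named in the series title. Ly6e, with 14.42 ± 0.22 (SD, n = 2) on the standard-diet label, 13.58 ± 0.07 (SD, n = 3) on cholesterol and 12.83 ± 0.22 (SD, n = 2) in wild type, had a log2 difference of 1.18 ± 0.19 (SE). Mylk differed by 1.63 ± 0.31, the vessel gene Ptprb by 1.26 ± 0.24, and Tnfsf10, which encodes the death ligand TRAIL and was below the negative control median on 6 arrays, by 1.61 ± 0.31. Zc3h15 stood at -1.06 ± 0.22 and Gk at -0.89 ± 0.24. Called lists were microglia (median 1.42, camera adjusted p = 1.67e-05), interferon response (median 0.64, camera adjusted p = 1.95e-05), endothelial genes (median 0.63, camera adjusted p = 0.00866) and immediate early genes (median 0.68, camera adjusted p = 0.0394). The adjusted p was 0.446 for each with an estimated correlation. Without CETP standard-diet replicate 4 the microglia median was 0.58 and still called, while the endothelial and immediate early calls were lost at 0.32 and 0.07. The interferon call was lost without wild-type replicate 3 (median 0.40). With the 5 CETP arrays as 1 group camera called microglia (median 1.30, adjusted p = 0.000425, with array medians of 3.77 in CETP standard-diet replicate 4 and 0.19 to 1.12 on the other 4 CETP arrays), interferon response (median 0.56, adjusted p = 0.00677) and endothelial genes (median 0.56, adjusted p = 0.0464). The adjusted p was 0.589 for each with an estimated correlation. By limma 0 features passed (smallest adjusted p = 0.491), and 1729 had an unadjusted p under 0.05.

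The authors' deposited table holds 1778 probe sets with signed folds, 1008 positive and 770 negative, and does not name its groups. Its folds equalled, within 0.0051, the difference of biweight averages between CETP standard-diet and CETP cholesterol-diet arrays for 98.5% of probe sets. When wild type entered the calculation, at most 0.337% of entries were equal. In the authors' deposited table the folds were 4.15 for Mpeg1, 3.48 for C1qa and 2.19 for Irf7 on the positive side, and -1.84 for Srebf2 and -1.71 for Srebf1 on the negative side.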

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

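All explanations in this part were tested only after the result was seen. The lists given first were called by camera in the comparison of the CETP diet groups, cholesterol minus standard diet. The list medians on the log2 scale were 0.52 for cholesterol synthesis, 0.47 for lipoprotein receptors, 0.52 for amyloid precursor processing and 0.38 for glycolysis and lactate transport. On the lower side they were -0.82 for interferon response, -0.69 for disease-associated microglia, -0.63 for the unfolded protein response, -0.51 for heat shock, -0.53 for immediate early genes, -1.22 for microglia, -0.53 for endothelial genes and -0.70 for choroid plexus. None of these 12 was called with an estimated correlation, and their genes were named because the authors had selected them for this difference. Only the reported genes of the fixed lists and of the naming rule were searched for a full ordering of the 3 groups, in either direction. For 3 of them every cholesterol-diet array lay above and every standard-diet array below the wild-type arrays. These were Pigt (difference 0.77), Ccl17 (0.75, below the negative control median on 5 arrays) and Sorl1 (0.51), and none of the 3 passed limma's test of the difference over all genes (adjusted p = 1.000). The authors had selected these 3 genes for a difference between the CETP diet groups. The naming rule also required that the arrays of Pigt and Ccl17 not overlap between these groups. Part of the ordering was thus fixed in advance. Groups of 2 or 3 arrays are too small for a test of single outlying arrays.

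Microglial genes were high in the CETP standard-diet group, mainly in replicate 4, where all 8 named microglial genes were highest, while in replicate 5 they lay within the range of the 5 arrays of the other groups. The far higher signal of this group may therefore be largely that of 1 array. That range includes cholesterol-diet arrays that were themselves above wild type. Their microglia medians over the wild-type mean were 1.04 in replicate 1, 0.19 in replicate 2 and 1.12 in replicate 3. A smaller rise over wild type was thus not limited to replicate 4. A smaller change shared by both animals stays open, because the median of replicate 5 was -0.35 ± 0.12 relative to the cholesterol-diet mean but 0.54 ± 0.16 relative to wild type (SE over the genes of 1 array). Microglial cells or their RNA carried into replicate 4 may account for it, since the smallest of the 8 rises there was 1.94, with C1qa at 13.62 and Tyrobp at 10.88, but the names come from the authors' selection, which keeps this test open. An immune response of that animal was not tested and stays open as well.

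Interferon response genes were high in both CETP standard-diet arrays, with median rises over the 5 arrays of the other groups of 1.17 in replicate 4 and 0.68 in replicate 5. In replicate 5 the interferon median exceeded the microglial one by 0.73 ± 0.22 (SE) over those 5 arrays but by 0.31 ± 0.26 over wild type, so microglial RNA stays open there. The interferon median exceeded the endothelial one by 0.36 ± 0.21 and 0.50 ± 0.27 in the same order, so endothelial RNA stays open too. These SEs are over the genes of 1 array, taken as independent, and do not measure the spread between animals. These tests rest on 1 array and on names the authors selected, of which 3 of the 6 interferon and 7 of the 8 microglial genes were below the negative control median on at least 1 array. Genotype and diet stay open, because their comparisons share the same 2 arrays. Camera also called a list in 28 of 100 simulated draws without any change, which held neither co-expression nor the authors' selection. An infection or another exposure was not tested.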

How the results depend on the processing

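The covariate for the hybridization spike-in level was chosen after seeing the data, and all other alternatives before. For the named genes, 1562 of 1573 alternative values kept their direction and their side of the threshold, 10 reversed and 1 passed. Much of this was fixed in advance. No named gene passed in the main fit, and genes chosen because their arrays did not overlap cannot reverse when an array is left out. The cause was not tested for any change below. With at least 1.5-fold at an unadjusted p under 0.05 the counts of features were 1431 for CETP_cholesterol against WT_standard, 956 for CETP_standard against WT_standard, 440 for CETP_cholesterol against CETP_standard and 1062 for the mean of the CETP groups against WT_standard. An adjusted p of 0.10 gave 0 in each. With an estimated correlation and with fry, 0 lists were called in any comparison. The number of arrays limits all of these values, and a group left with 1 array took its spread from the others.

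For CETP_cholesterol against WT_standard, 0 lists were called, which became 2 with only the groups compared and 4 each with array weights, the replicate block and the animal number block. The blocks could be fitted for this comparison only. The replicate block gave 7 features, among them Frzb (3.96) and Podxl (2.26), named after their values were seen, with 1 residual degree of freedom. It also moved the immediate early median to -0.0081. Same-numbered arrays had residual correlations of 0.00838 and 0.0373 in 2 pairs, so the numbers were not taken as a pairing. The spike-in covariate called 1 list. It reversed lipoprotein receptors (-0.35), glycolysis (-0.33), disease-associated microglia (0.35), Srebf1 (-0.069), Apoe (0.017), Ebp (0.23), Sorl1 (-0.12), Lrp1 (-0.19), Pgam1 (-0.35) and Btg2 (0.48).

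Leaving out each array gave 0 to 3 called lists there, the 3 without CETP_cholesterol replicate 2. Medians ranged from -0.041 to 0.44 for SREBP2 regulation, -0.041 to 0.41 for liver X receptor targets, -0.013 to 0.27 for lipoprotein receptors, -0.044 to 0.51 for interferon response and -0.010 to 0.37 for immediate early genes. Mylip, which is in both the SREBP2 and the liver X receptor list and set their lowest median, ranged from -0.041 to 0.44. Irf7 ranged from -0.065 to 0.62 and Btg2 from -0.25 to 0.046. The lists that gained a call in these alternatives were unfolded protein response, microglia, amyloid precursor processing, interferon response, pan-reactive astrocyte, choroid plexus and glycolysis.

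For CETP_standard against WT_standard, leaving out each array gave 0 to 9 features and 1 to 8 lists, with disease-associated microglia from -0.079 to 1.28. Its 9 features came without CETP_standard replicate 5, which leaves replicate 4 alone, and are genes such as Tyrobp, Trem2, Cst7 and Mpeg1. Pan-reactive, disease-associated microglia and immediate early lists lost their call without either wild-type array, pan-reactive genes also without CETP_cholesterol replicate 3 and with the spike-in covariate, and all but interferon response without CETP_standard replicate 4.

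For CETP_cholesterol against CETP_standard, the ranges were 0 to 14 features, 4 to 12 lists, -1.23 to 0.030 for immediate early genes and -2.88 to 0.35 for microglia. Only amyloid, choroid plexus, interferon and unfolded protein lists kept their call without CETP_standard replicate 4. Calls were also lost by amyloid, choroid plexus and glycolysis without CETP_standard replicate 5, by glycolysis and lipoprotein receptors without CETP_cholesterol replicate 3, by immediate early genes without CETP_cholesterol replicate 2, and by choroid plexus and lipoprotein receptors with array weights. The spike-in covariate left 7 lists and ended the calls of cholesterol synthesis, lipoprotein receptors, glycolysis, heat shock and endothelial genes.

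For the mean of the CETP groups against WT_standard, the ranges were 0 to 3 features, again without CETP_standard replicate 5 (Tyrobp, Slc15a3 and Mpeg1), and 2 to 6 lists. Immediate early genes lost their call without either wild-type array, without CETP_standard replicate 4, with the CETP arrays as 1 group, with quantile normalization and with the spike-in covariate. Endothelial genes lost it without WT_standard replicate 2 or CETP_standard replicate 4, and interferon response without WT_standard replicate 3. Apart from the estimated correlation and fry, no other called list lost its call.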

Other observations

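The tests in this part were chosen only after the result was seen. Further genes of phagocytes, outside the fixed lists, were high in CETP standard-diet replicate 4, as chosen after their values were seen. Mpeg1, which encodes a pore protein of macrophages, measured 10.72 there against 6.90 in replicate 5, and Bcl2a1a, a survival gene of immune cells, 12.68 against 7.93. Cst7 and Clec7a of the disease-associated microglia list measured 10.46 and 8.79 there and were below the negative control median on the other 6 arrays. Of the 1008 probe sets that are higher in the authors' deposited table, 185 were above all 5 other arrays in both standard-diet animals, 238 in replicate 4 only, 290 in replicate 5 only and 295 in neither. Of the 72 with a fold of at least 2 the counts were 17, 34, 18 and 3 in the same order.

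The first principal component, 30.0% of the variance, followed the level of the 4 hybridization spike-in controls, which are added to every sample alike. Across the 7 arrays Pearson's r was 0.864 (exact permutation p = 0.0149) and Spearman's rho 0.821 (exact permutation p = 0.0341), and r was 0.551 without the 2 arrays farthest from the median, in 1 relation tested. An array-wide technical difference may therefore contribute to this component. The cholesterol diet as its whole cause stays open, since only 1 of the 3 cholesterol-diet arrays, replicate 2 at -10.1, lay within the range of the other 4 arrays (-28.7 to 6.81), while replicates 1 and 3 lay beyond it at 13.8 and 51.4, and the spike-in level was also above wild type on all 3 cholesterol-diet arrays. Of the 770 probe sets that are lower in the authors' deposited table, replicate 2 was the lowest cholesterol-diet array for 70.4%, against 34.1% of all probe sets. The table's folds matched biweight averages of these same arrays, which give an outlying array less weight. The share among all probe sets is therefore not a like reference, and the difference was not tested.

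Between the CETP diet groups 1604 probe sets differed by at least 1.4-fold in their means, and the highest count among other splits of these 5 arrays was 2811. Of the 10 splits 6 gave as many as the real one, itself included, and 10 splits are too few for a share under 0.05. Between the cholesterol-diet group and wild type the count was 3352 and the highest other 3678, with 2 of 10 splits giving as many, again too few. Between the CETP standard-diet group and wild type the count was 2790, below both other splits (2978 and 3241), so all 3 splits gave as many. Olfactory and vomeronasal receptor genes made up 140 entries of the authors' deposited table, 36 higher and 104 lower on the standard-diet label. That is 74.3% lower, against 40.7% of all other entries, in a group of genes chosen after its values were seen and not tested.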
